A study of Melianthus elongatus with 11 samples.

How the data were processed

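Leaves and nectaries of Melianthus minor were collected outdoors into RNAlater, a solution that preserves RNA. Per the labels' protocols, RNA was extracted with the RNAqueous Micro kit and treated with DNase, and libraries were sequenced on a NovaSeq instrument in paired-end runs. Per the submitters' processing notes, kallisto 0.46.1 was used, a program that assigns reads to transcripts and divides reads shared by similar transcripts among them. The deposited values are a normalised read signal, called normalised read counts by the authors in the file headers, in 1 column per library. How the authors scaled the libraries, built the contigs or chose those listed is not given in the sources used here. The values are not whole, show no common step and sum to 631454 to 1168300 per library. They were therefore treated neither as raw counts nor as CPM or TPM values. The depth in reads is unknown, and no interval or floor that needs it is given. The table lists 68651 contigs with numbers up to 462675, of which 67753 have a closest Arabidopsis locus (16092 distinct loci). No comparison made by the authors was in the table. Its rows run nearly in order of the difference between codes 1 and L, largest first (Spearman's rho of row number and difference, -0.981). Whether contigs were also chosen by that difference is unknown. Shares of contigs called are therefore shares of this table, not of all transcripts.

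Groups were taken from the first part of the library code that each sample's description and the table's columns share. The filed titles, tissues and stages cross these codes, and the title and stage of 2-A disagree, so grouping by filed tissue and stage was run as an alternative. Nothing says that libraries of 1 code came from separate plants, so p-values measure only the spread between these libraries, which may be technical. The comparisons were code 1 with 0, 2 with 1, 2 with 0, the mean of codes 0, 1 and 2 with L, and each code singly with L as counts. These comparisons share libraries, so their results are not independent of each other.

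Contigs with a value of at least 10 in at least 2 libraries were kept (26053). Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with the empirical Bayes trend, 1 mean per code and all 11 libraries in 1 fit. Tests were two-sided with Benjamini-Hochberg adjustment over the contigs kept, and a contig was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Log2 differences are on the log2(value + 1) scale, which understates the change of low contigs, and a value listed at 0 may be a failed estimate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Tested on simulated data made from the real means, with 210 contigs changed, the procedure called 32.9%, 65.7% and 84.3% of 70 contigs at each log2 change of 1.5, 2 and 3 for code 1 with 0. It called 54.3%, 75.7% and 94.3% for code 2 with 1, and 68.6%, 80.0% and 95.7% for codes 0, 1 and 2 with L. Among 25843 unchanged contigs, 0.0310%, 0.0619% and 0.0387% were called. The changed contigs were drawn only from those above a set mean level. The noise was normal, independent between libraries and of the same spread in every code. In the data, libraries of code 2 were less alike (Pearson's r of log2 values, 0.767 to 0.878) than those of code 1 (0.930 to 0.967). These shares therefore do not describe low contigs, comparisons in which many contigs change, or codes of unlike spread.

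Fixed gene lists, 22 with 646 Arabidopsis loci, covered photosynthesis and the Calvin cycle, sugar transport and sucrose metabolism, starch synthesis, starch breakdown, nectary and flower development regulators, jasmonate, shikimate and gallate glucosylation, phenylpropanoids and lignin, flavonoids and anthocyanins, iron homeostasis, class III peroxidases, superoxide and hydrogen peroxide enzymes, defence proteins, cell division, senescence, autophagy, proton pumps with aquaporins and vesicle export, heat shock, and markers of pollen and tapetum, vascular tissue, epidermis and cuticle, and stomata. Of their loci, 366 had a kept contig (1121 contigs). Contig counts of a list are therefore not counts of genes. The 80 regulator contigs came from 16 loci, the 247 photosynthesis contigs from 58, the 27 superoxide contigs from 7 and the 22 defence contigs from 8. The 21 lists with at least 5 contigs were tested with limma's camera, which compares a list with all other contigs, at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of each comparison. With the preset correlation 8, 5, 12 and 9 lists passed in the 4 comparisons, and with an estimated correlation 1, 0, 1 and 0.

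Named contigs followed a rule. In each list and direction it took the called contig with the largest difference and no overlap between libraries (up to 2 for the shikimate, iron, peroxidase, superoxide and sugar lists). It added the 5 annotated contigs with the largest rise and the 5 with the largest fall among calls without overlap and above the median level. It also took the highest contig for SWEET9, CWINV4, SPS2F, CRC, MYB21, MEE32, UGT84A2, FER1, RBCS1A and LHCB1.1 and the 3 highest peroxidase contigs, whatever their call. The groups, tests, lists, rule and alternatives were fixed before the data were examined.

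The alternatives were pseudocounts of 0.1 and 10, no filter and a filter of 50, libraries rescaled to equal totals or by the median ratio, only the compared codes in the fit, the replicate letter as a block, robust moderation, library weights, groups as filed, no minimum difference, 1 contig per locus, and leaving out each library. Removals of 2-A with 2-C, L-A with 2-C, and 1-A with 1-B were added after seeing the data. The planned count models were not run, since the values are not counts.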

Results

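The nectar of Melianthus minor, a shrub also known as M. elongatus, is black, and the submitters' title likens its pigment to iron-gall ink, a dark complex of iron with derivatives of gallic acid. RNA was taken from leaves and from nectaries, the glands that secrete nectar, of plants grown in an arboretum, and 11 libraries were analysed. The library codes form 4 groups: code 0 with 2 libraries (0-A, 0-B), code 1 with 3 (1-A, 1-B, 1-C), code 2 with 3 (2-A, 2-B, 2-C) and code L with 3 (L-A, L-B, L-C). What a code stands for is not given in the sources used here. The filed labels call 0-A, 0-B and 1-A mature leaf, 1-B and 1-C presecretory nectary, the code 2 libraries secretory nectary and the code L libraries postsecretory nectary. These labels cross the codes, and the title of 2-A says presecretory where its stage says secretory. The comparisons below are therefore between codes, and no tissue or stage is assigned to a code.

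The values were the authors' normalised read counts for 68651 contigs, each with its closest Arabidopsis locus where one was listed. A contig is called here by the Arabidopsis gene it most resembles. Several contigs can share 1 locus and similar contigs can share reads, so the split of values between contigs of the same locus is uncertain. Column totals ran from 631454 in L-B to 1168300 in 1-C, and the code L totals (642324, 631454 and 916467) were the lowest of the 11. The depth in reads is unknown. Across the 26053 contigs kept, Pearson's r of log2 values between libraries of 1 code was 0.945 in code 0, 0.930 to 0.967 in code 1, 0.767 to 0.878 in code 2 and 0.904 to 0.922 in code L. Between codes, r was 0.761 to 0.897 for codes 1 and 2, 0.522 to 0.551 for codes 0 and 1, and 0.246 to 0.376 for codes 2 and L. These coefficients are across contigs, which are not independent replicates.

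Library 1-A, filed as leaf, had r of 0.930 and 0.967 with 1-B and 1-C, filed as presecretory nectary, and at most 0.544 with 0-A and 0-B, filed as leaf. The contigs of the photosynthesis and Calvin cycle list had a median value of 12.5 in 0-A, 14.3 in 0-B and 10.0 in 1-A, the 3 libraries filed as leaf. In L-A, L-B and L-C, filed as postsecretory nectary, that median was 181, 189 and 267. The list of nectary and flower development regulators had mean log2 values of 4.33 to 4.92 in codes 0, 1 and 2 and of 0.70 to 1.18 in code L.

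**Figure D1:**
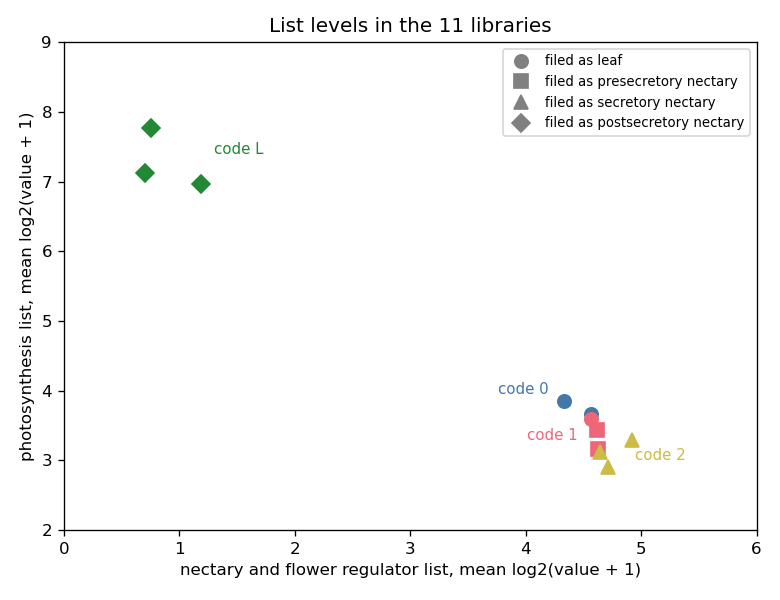
Mean log2(normalised value + 1) of the photosynthesis list (y axis) against that of the nectary and flower development regulator list (x axis), 1 point per library, with colour for the code and shape for the filed tissue and stage. The 3 code L libraries lie at 6.97 or above on the y axis, and the other 8 libraries at 3.86 or below.

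The comparison of code 1 with code 0 asks which transcripts separate these groups of 3 and 2 libraries. A contig like SWEET9, the sucrose exporter that nectar secretion needs in Arabidopsis, rose from 1.85 ± 1.43 (SD, n = 2) in code 0 to 2441 ± 553 (SD, n = 3) in code 1. The log2 difference was 9.81 (SE 1.14; limma, adjusted p = 1.34e-04; Mm6, AT2G39060). Contigs like the ferritins FER1 and FER4, which store iron, also rose, and most of the called cell division contigs fell. A contig like CRC, a YABBY transcription factor required for nectary development, fell from 1073 ± 201 (SD, n = 2) to 78.0 ± 32.7 (SD, n = 3), by 3.83 on the log2 scale (limma, adjusted p = 0.00507; Mm734, AT1G69180). A contig like UGT84A2, a glucosyltransferase of phenolic acids, fell from 756 ± 141 to 10.6 ± 2.54 (SD), by 6.04 on the log2 scale (limma, adjusted p = 0.00426; Mm2212, AT3G21560).

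Of the 79 contigs of the sugar transport and sucrose metabolism list, 30 rose, 8 fell and 41 were not called (31 and 8 adjusted over the list alone; camera adjusted p = 3.98e-04, and adjusted p = 0.359 with an estimated correlation). Among them a contig like SUS1, a sucrose synthase, rose by 5.26 (SE 0.40; Mm7610), from 3.77 to 183. A contig like the cell wall invertase CWINV4 (Mm213688) fell by 3.99, a call lost without 0-A (-3.69), 0-B (-4.28), 1-A (-3.32) or 1-C (-3.73). The highest contig like SPS2F, a sucrose phosphate synthase, differed by 0.64 and was not called (limma, adjusted p = 0.0695; Mm108508). In starch synthesis 3 of 29 contigs rose and 6 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.00497, and adjusted p = 0.742 with an estimated correlation). A contig like APL4, a subunit of ADP-glucose pyrophosphorylase, fell by 4.39 (Mm25035), while a contig like starch synthase SS2 (Mm242234), listed at 0 in both code 0 libraries, was at 31.7, 24.7 and 36.5 in code 1. In starch breakdown 6 of 41 contigs rose and 9 fell (6 and 10 adjusted over the list alone; camera adjusted p = 0.0857). The phosphoglucan water dikinase PWD (Mm2704) rose by 4.03 and the amylase AMY3 (Mm15272) fell by 4.36.

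The shikimate pathway makes aromatic amino acids and is the source of gallic acid. Of the 52 contigs of the shikimate and gallate glucosylation list, 5 rose, 23 fell and 24 were not called (6 and 26 adjusted over the list alone; camera adjusted p = 4.68e-05, and adjusted p = 0.359 with an estimated correlation). A contig like DHS1, the entry enzyme of the pathway, was at 176 and 86.4 in 0-A and 0-B and listed at 0 in all 3 code 1 libraries. Its call was lost without 0-A (log2 difference -6.45; Mm247). Contigs like the shikimate kinases SK2 and SK1 rose by 3.47 and 3.31 (Mm406526 and Mm212102), calls lost without any 1 of 0-A, 0-B, 1-A and 1-C (3.02 to 3.93). That of Mm406526 was also lost without 2-B (3.47), at equal totals (3.29), after median ratio scaling (3.3) and with a pseudocount of 0.1 (3.76). The highest contig like MEE32, which makes shikimate, differed by -0.87 and was not called (limma, adjusted p = 0.342; Mm37). In the flavonoid and anthocyanin list 1 of 26 contigs rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.00379, and adjusted p = 0.580 with an estimated correlation). In the phenylpropanoid and lignin list 11 of 30 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.297). Contigs of 1 locus could move apart: of those like the methyltransferase COMT1, Mm228 rose by 3.90 and Mm22818 fell by 4.72.

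In the iron homeostasis list 16 of 72 contigs rose and 9 fell, also when adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.591). The FER1-like contig rose from 87.5 ± 21.2 (SD, n = 2) to 2067 ± 402 (SD, n = 3), by 4.55 (SE 0.58; limma, adjusted p = 2.44e-04; Mm4874). The FER4-like contig rose from 7.38 to 643, by 6.35 (Mm11195). Contigs like NAS1, which makes the iron chelator nicotianamine, and OPT3, a phloem transporter of iron, fell by 4.90 and 3.75 (Mm27542 and Mm78887). Of the 24 class III peroxidase contigs, secreted enzymes that oxidise phenolics with hydrogen peroxide, 4 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.211). The peroxidase contig Mm1 (closest to AT4G16270) rose from 61.1 ± 14.5 (SD, n = 2) to 3222 ± 907 (SD, n = 3), by 5.68, and Mm276 (AT4G26010) rose by 7.37, while Mm562 (AT4G21960) fell by 2.8. Among the enzymes of superoxide and hydrogen peroxide 5 of 27 contigs rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.424). A germin-like contig near GLP3 fell by 8.10 (Mm200630), and a catalase contig near CAT2 rose by 3.44 (Mm48788).

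The cell division list gave the lowest p of the lists: 2 of its 22 contigs rose, 15 fell and 5 were not called (2 and 16 adjusted over the list alone; camera adjusted p = 2.39e-09). It was the only list of the 21 tested to pass in this comparison with an estimated correlation (adjusted p = 0.0156). A contig like the cyclin CYCD3;2 fell from 93.8 to 0.312, by 6.17 (Mm161094), and one like CYCB1;2 rose by 3.57 (Mm311744; not called without 0-A, at 3.3). In the senescence list 21 of 43 contigs rose and 1 fell (27 and 2 adjusted over the list alone; camera adjusted p = 1.67e-04, and adjusted p = 0.359 with an estimated correlation). In the defence protein list 10 of 22 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00125, and adjusted p = 0.324 with an estimated correlation). Of the 247 photosynthesis contigs 9 rose and 40 fell (9 and 37 adjusted over the list alone; camera adjusted p = 0.00177, and adjusted p = 0.742 with an estimated correlation). A contig like RBCS1A, a small subunit of Rubisco, fell by 2.45 (Mm17414), while another of the same locus, listed at 0 in code 0, was at 36.2, 55.4 and 50.5 in code 1 (Mm371224, a rise of 5.57, not called without 0-A or without 0-B, at the same difference).

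Among the regulators of nectary and flower development 23 of 80 contigs rose and 19 fell (24 and 20 adjusted over the list alone; camera adjusted p = 0.643). The contigs like MYB21, a jasmonate-responsive factor of stamens and nectaries, rose by 5.64 (Mm4571) and 4.97 (Mm414). The second call was lost without 0-B (3.18). A contig like SHP1, a MADS-box factor of carpels, was at 91.7 and 180 in code 0 and listed at 0 in every library of codes 1 and 2 (Mm250579). In the jasmonate list 17 of 74 contigs rose and 24 fell (19 and 28 adjusted over the list alone; camera adjusted p = 0.283), with the lipoxygenases LOX2 (Mm13) up by 6.68 and LOX3 (Mm12238) down, at -5.19. Among the contigs with the largest differences of all, one like an aldehyde oxidase, listed at 0 in code 0, was at 3213, 1930 and 4410 in code 1 (Mm114371), and a glucanase contig rose by 8.97 (Mm193). A lipid-transfer protein contig fell by 8.44 (Mm42146) and an arabinogalactan protein contig fell by 8.26, from 391 to 0.300 (Mm134411).

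In all, limma called 6734 of 26053 contigs, 3551 higher and 3183 lower in code 1. The larger side turned in 5 settings, with 3074 higher and 3922 lower at equal totals, 3141 and 3615 after median ratio scaling, 6299 and 6888 with no filter, 1931 and 2024 without 0-A, and 2709 and 2722 without 1-A. The median difference of all kept contigs was 0.10 as deposited and -0.05 with equal totals. The count was 3955 without 0-A and 4041 without 0-B, where 1 library stood for code 0. It was 2957 without both 1-A and 1-B, an alternative chosen after seeing the data that also ended the calls of Mm1, Mm2212, Mm734, Mm414, Mm213688, Mm247, Mm406526, Mm212102 and Mm371224. A pseudocount of 0.1 ended the calls of Mm734 (-3.84) and Mm213688 (-4.93). With 1 contig per locus the photosynthesis, starch synthesis, shikimate and flavonoid lists were not called (medians -0.30, -0.72, -0.71 and -0.60), nor with a filter of 50 starch synthesis, flavonoids and senescence (-0.87, -0.99 and 1.72). With libraries grouped by their filed tissue and stage, limma called 0 contigs (3557 at an unadjusted p under 0.05).

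**Figure D2:**
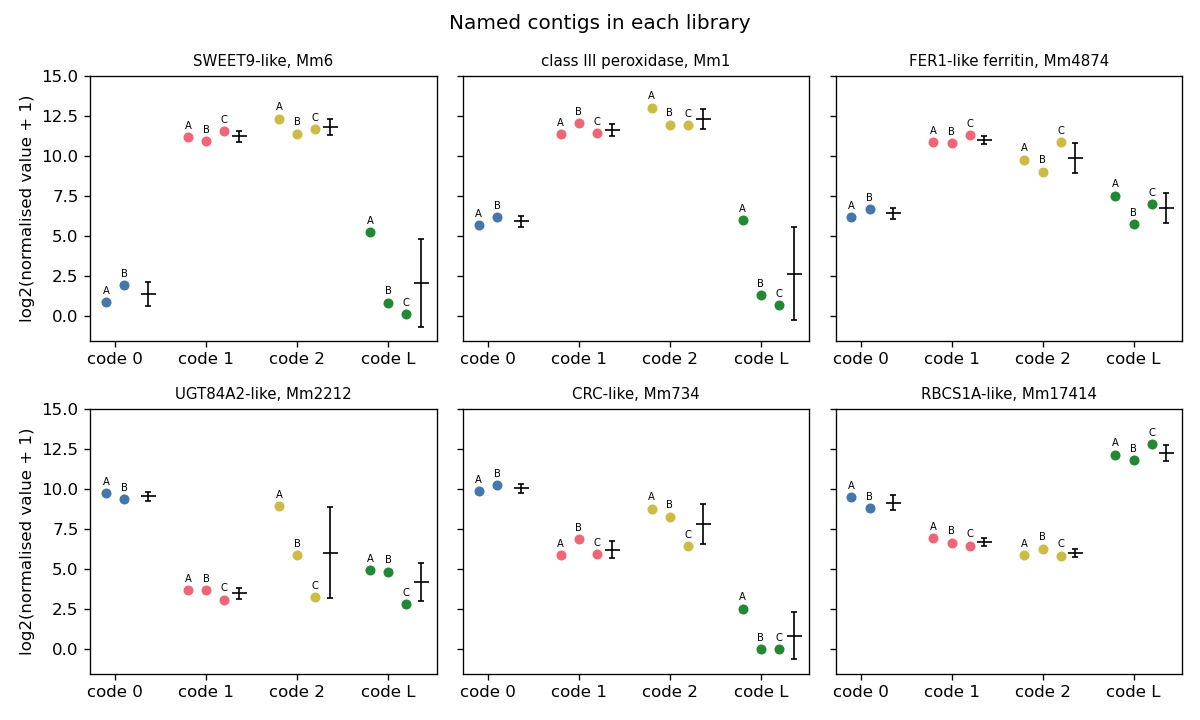
Log2(normalised value + 1) of 6 named contigs (y axis) in each library, by code (x axis), with the letter of each library over its point and the mean ± SD of each code as a black bar beside the points. The SWEET9-like contig is at 1969 or above in every library of codes 1 and 2, and at 36.8 or below in codes 0 and L.

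The comparison of code 2 with code 1 concerned the pair of groups closest to each other. Markers of pollen and of the tapetum, the layer of the anther that feeds pollen, were lower in code 2: of 23 contigs 7 were called, all lower (15 adjusted over the list alone, all lower; camera adjusted p = 1.67e-12, and adjusted p = 0.719 with an estimated correlation). The mean log2 value of that list was 4.50 in 1-A and 4.42 in 1-B, 3.33 in 1-C and 2.1 to 2.71 in code 2. A contig like AGP6, an arabinogalactan protein of pollen, fell from 85.2 ± 46.1 to 6.40 ± 0.788 (SD, n = 3 each), by 3.35 (limma, adjusted p = 0.0179; Mm129086). The SWEET9-like contig was at 2441 in code 1 and 3754 ± 1300 (SD, n = 3) in code 2 and was not called (limma, adjusted p = 0.877).

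Each other fixed list held at most 3 calls. In the shikimate and gallate list 1 of 52 contigs rose, the same number adjusted over the list alone (camera adjusted p = 1.62e-04, and adjusted p = 0.722 with an estimated correlation). It was like UGT84A1, a glucosyltransferase of phenolic acids, at 30.0 ± 3.11 in code 1 and 103 ± 56.3 (SD, n = 3 each) in code 2, a rise of 1.62 (Mm18040). The UGT84A2-like contig was at 494 in 2-A, 58.7 in 2-B and 8.59 in 2-C against 10.6 ± 2.54 (SD, n = 3) in code 1 and was not called (Mm2212; limma, adjusted p = 0.369), but was called with library weights (log2 difference 3.04) and without 2-C (3.92). The phenylpropanoid list had 0 calls by limma (11 of 30 at an unadjusted p under 0.05; 4 higher and 1 lower adjusted over the list alone) and passed as a list, upward (camera adjusted p = 0.00722). The photosynthesis list, with 0 calls by limma over all contigs and over the list alone (43 of 247 at an unadjusted p under 0.05), passed downward (camera adjusted p = 0.00722). The epidermis and cuticle list, 1 of 19 lower (4 adjusted over the list alone), passed downward (camera adjusted p = 0.00763). For these 3 lists the adjusted p was 0.979 with an estimated correlation. Of contigs chosen for size, one like an adenosylmethionine decarboxylase, an enzyme of polyamine synthesis, rose from 171 to 1300, by 2.87 (Mm20), and one like an RNA-binding protein fell from 206 to 8.86, by 4.89 (Mm326622). The aldehyde oxidase contig fell from 3184 to 207, by 4.80 (Mm114371).

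In all, limma called 304 contigs, 48 higher and 256 lower in code 2, and the count depended on single libraries. It was 0 without 1-A (2239 at an unadjusted p under 0.05), so every call named here was lost, with log2 differences of -3.03 for Mm129086, 1.64 for Mm18040, 2.90 for Mm20, -4.88 for Mm326622 and -4.75 for Mm114371. It was 112 without 1-B, 30 without 2-A, 823 without 2-B, 1483 without 2-C, and 175 without 0-A or without 0-B, which enter only the estimate of the spread. The calls of Mm18040 and Mm114371 were also lost in the removal of any other library except 2-B and 2-C, with values of 1.21 to 1.68 and of -5.18 to -4.52, and that of Mm129086 without 2-A (-3.40). With only the libraries of codes 1 and 2 in the fit the count was 1, none of the contigs named here, and with libraries grouped as filed it was 0 by limma (1263 at an unadjusted p under 0.05). Without 1-A the photosynthesis and epidermis lists were no longer called (medians -0.17 and -0.40), nor without 2-C the phenylpropanoid and epidermis lists (medians 0.41 and -0.04). With 1 contig per locus the shikimate, phenylpropanoid and epidermis lists were not called (medians 0.50, 0.76 and -0.60), nor with no filter the photosynthesis, phenylpropanoid and epidermis lists (-0.14, 0.17 and -0.19). Library weights ended the calls of the phenylpropanoid and epidermis lists (0.18 and -0.23), and a filter of 50 that of the epidermis list (-0.56). The call of Mm18040 was lost with no filter (1.62), with median ratio scaling (1.64) and with a pseudocount of 0.1 (1.64), which also ended those of Mm326622 (-5.18) and Mm114371 (-4.83).

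The comparison of code 2 with code 0 sets 3 libraries against 2. The SWEET9-like contig was higher in code 2 by 10.41 (SE 1.14; limma, adjusted p = 1.10e-04; Mm6), and a contig like the sucrose phosphate synthase SPS3F rose from 5.99 ± 1.28 (SD, n = 2) to 227 ± 77.7 (SD, n = 3), by 4.97 (Mm29). Of 22 cell division contigs 16 were called, all lower (17 adjusted over the list alone, all lower; camera adjusted p = 3.97e-11, and adjusted p = 0.00923 with an estimated correlation). A contig like the plasma membrane proton pump AHA2, listed at 0 in code 0, was at 809, 479 and 172 in code 2 (Mm8). The CRC-like contig differed by -2.23 and the UGT84A2-like contig by -3.51, and neither was called (Mm734 and Mm2212; limma, adjusted p = 0.0647 and 0.0580). Both were called with a pseudocount of 10 (-2.17 and -3.14), with library weights (-1.86 and -3.16) and without 2-A (-2.70 and -4.97), Mm734 also without L-A (-2.23) or without both L-A and 2-C (-1.53), and Mm2212 also without both 2-A and 2-C (-3.65).

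Of the 79 sugar contigs 24 rose and 8 fell (26 and 8 adjusted over the list alone; camera adjusted p = 0.00344). Of 43 senescence contigs 19 rose and 3 fell (20 and 4 adjusted over the list alone; camera adjusted p = 0.00344). A contig like SAG21, a protein of senescence and oxidative stress, rose from 200 to 5483, by 4.77 (Mm22). Of 30 phenylpropanoid contigs 11 rose and 2 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0222). Of 22 defence contigs 8 rose and 2 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.0298). A WRKY40-like contig rose by 2.95 (Mm1056). Of 247 photosynthesis contigs 3 rose and 51 fell (3 and 47 adjusted over the list alone; camera adjusted p = 3.29e-06). Of 29 starch synthesis contigs 1 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.00415). Of 26 flavonoid contigs 2 rose and 10 fell (2 and 11 adjusted over the list alone; camera adjusted p = 0.00601). Of 19 epidermis and cuticle contigs 1 rose and 10 fell, also when adjusted over the list alone (camera adjusted p = 0.00776). With an estimated correlation the adjusted p of these 8 lists was 0.591.

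In the shikimate and gallate list 1 of 52 contigs rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.0110, and adjusted p = 0.591 with an estimated correlation). A contig like chorismate synthase fell by 2.95 (Mm73957), and one like the arogenate dehydratase ADT1, which leads to phenylalanine, rose by 2.48 (Mm3254). The MEE32-like contig was at 228 ± 36.7 (SD, n = 2) in code 0 and at 709, 342 and 106 in 2-A, 2-B and 2-C, and was not called (Mm37; limma, adjusted p = 0.697), while another contig of that locus fell by 3.41 (Mm5660; not called without 0-A, at -3.26, or with only codes 0 and 2 in the fit). In starch breakdown 6 of 41 rose and 13 fell (7 and 14 adjusted over the list alone; camera adjusted p = 0.0316). Of 23 pollen and tapetum contigs 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0149). The adjusted p of both was 0.598 with an estimated correlation. The iron list was not called, with 12 of 72 higher and 8 lower (13 and 8 adjusted over the list alone; camera adjusted p = 0.345). Its FER1, FER2 and FER4 contigs rose by 3.45, 4.12 and 5.24 (Mm4874, Mm815 and Mm11195), and its NAS1 and OPT3 contigs fell by 3.76 and 3.64 (Mm27542 and Mm78887). Of 24 peroxidase contigs 4 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.112), with Mm1 higher by 6.37 and Mm276 by 7.81. Both MYB21-like contigs rose, Mm4571 by 6.21 and Mm414 by 5.47, the latter not without 0-B (3.68).

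In all, limma called 6252 contigs, 2990 higher and 3262 lower in code 2 (2496 and 4098 with equal totals). The larger side turned with library weights (4146 higher and 3725 lower), with a filter of 50 (1094 and 860), without 0-B (1702 and 1597), without 2-C (3710 and 3498), without both 2-A and 2-C (3034 and 2442) and without both L-A and 2-C (3746 and 3585). The median difference of all kept contigs was 0.05 as deposited and -0.11 with equal totals. The count was 3551 without 0-A, 3299 without 0-B, and 4075 with only codes 0 and 2 in the fit. It was 0 by limma with libraries grouped as filed (5277 at an unadjusted p under 0.05). Without 2-C the sugar, starch breakdown, shikimate, phenylpropanoid, flavonoid, defence, pollen and epidermis lists were no longer called (medians 0.59, -0.62, -0.35, 0.93, -0.69, 1.25, -0.52 and -1.11), and without 0-A starch breakdown was not (-0.57). With 1 contig per locus the starch synthesis, starch breakdown, shikimate and flavonoid lists were not called (-0.67, -0.64, -0.11 and -0.89), and with a filter of 50 only the photosynthesis, sugar and shikimate lists were, with too few cell division contigs left to test. Phenylpropanoids were not called with no filter (0.60) or library weights (0.71), nor pollen with library weights (-0.80), nor starch breakdown with equal totals (-0.98).

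The comparison of codes 0, 1 and 2 with code L separated the libraries most. Photosynthesis contigs were higher in code L: of 247, 231 were lower in codes 0, 1 and 2 and 5 higher, the same numbers adjusted over the list alone (camera adjusted p = 1.37e-81, and adjusted p = 0.0519 with an estimated correlation), with a median log2 difference of -3.91. The RBCS1A-like contig was at 5110 ± 1822 (SD, n = 3) in code L against 584, 104 and 64.0 in codes 0, 1 and 2, a log2 difference of -4.97 (SE 0.26; limma, adjusted p = 1.65e-07; Mm17414), while one like the bisphosphatase SBPASE was higher in codes 0, 1 and 2, at 3.08 (Mm1955). Regulators of nectary and flower development went the other way: 75 of 80 contigs were called, all higher in codes 0, 1 and 2 (77 adjusted over the list alone, all higher; camera adjusted p = 9.10e-09, and adjusted p = 0.0931 with an estimated correlation). The CRC-like contig was at 1.61 ± 2.79 (SD, n = 3) in code L, a difference of 7.19 (Mm734), and contigs like the floral MADS-box factor SEP1 and MYB21 differed by 7.30 and 6.65 (Mm1125 and Mm414).

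Of the 5 contigs furthest toward code L, 4 were like a carbonic anhydrase of the chloroplast; the furthest, Mm322422, was at 2612, 1505 and 3171 in code L and at 2.36 or below elsewhere, a difference of -10.84. A contig like Rubisco activase differed by -7.87 (Mm156864) and one like LHCB1.1, a light-harvesting protein, by -2.98 (Mm3020). Among contigs furthest toward codes 0, 1 and 2 were one like a plasma membrane cation-binding protein, at 8.42 (Mm406), and one like the cell wall invertase CWINV2, at 8.02 (Mm3). Of 79 sugar contigs 55 were higher and 8 lower in codes 0, 1 and 2 (56 and 8 adjusted over the list alone, camera adjusted p = 0.0545). The sugar median was 2.25 as deposited and 1.47 after median ratio scaling. The SWEET9-like contig differed by 6.08 (Mm6; 7.66 without L-A), with values of 0.84 and 2.86 in code 0 and of 36.8, 0.806 and 0.105 in L-A, L-B and L-C. One like SWEET11, a sucrose exporter of phloem loading in leaves, differed by -3.24 (Mm82124). Of 19 epidermis and cuticle contigs 14 were higher in code L and 2 lower, the same numbers adjusted over the list alone (camera adjusted p = 9.85e-09, and adjusted p = 0.333 with an estimated correlation), among them GPAT6 at -3.54 (Mm88887) and, the other way, CER1 at 3.26 (Mm10296).

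Of 52 shikimate and gallate contigs 28 were higher and 4 lower in codes 0, 1 and 2 (26 and 4 adjusted over the list alone; camera adjusted p = 0.787). The median of that list was 1.69 as deposited and 0.56 after median ratio scaling. The UGT84A2-like contig differed by 2.17 (limma, adjusted p = 0.0480; Mm2212), with a mean of 21.2 in code L and a lower one, 10.6, in code 1. This call was lost without any 1 of 0-A, 0-B, 1-A, 1-B, 1-C, 2-B, L-A, L-B and L-C (1.47 to 2.54) and after equal totals (1.64), median ratio scaling (1.00), with a pseudocount of 0.1 (2.2) or with no filter (2.17). The MEE32-like contig differed by 1.86 (Mm37; 0.65 and not called after median ratio scaling), and contigs like DHS2 and SKL1 differed by -2.22 and -2.06 (Mm128412 and Mm77575). Of 72 iron contigs 31 were higher and 19 lower, also when adjusted over the list alone (camera adjusted p = 0.0837; median 0.93 as deposited and -0.21 after median ratio scaling). The FER1-like contig differed by 2.34 (Mm4874; mean of 87.5 in code 0 and 122 in code L), the NAS1-like contig by 4.55 (Mm27542) and one like the ferric reductase FRO4 by -4.41 (Mm196037). Of 24 peroxidase contigs 15 were higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.787). The peroxidase median was 1.81 as deposited and 0.89 after median ratio scaling. Mm1 differed by 7.28, Mm562 by 4.01 and Mm79448 by -2.75. Of 27 contigs of superoxide and hydrogen peroxide enzymes 9 were higher and 10 lower, also when adjusted over the list alone (camera adjusted p = 0.00602, downward, and adjusted p = 0.490 with an estimated correlation). The list's median was 0.51 (-0.71 after median ratio scaling) and its mean -1.11. A germin-like contig near GLP3 was at 1305 ± 135 (SD, n = 3) in code L, a difference of -8.13 (Mm172849).

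Because most contigs were higher in codes 0, 1 and 2, camera could call a list downward whose median was above 0. It did so for starch synthesis (10 higher and 6 lower of 29, also when adjusted over the list alone; median 0.61), flavonoids (7 and 8 of 26, also when adjusted over the list alone; median 0.40) and senescence (20 and 11 of 43, also when adjusted over the list alone; median 0.53), each at an adjusted p of 0.0445, and adjusted p = 0.776, 0.694 and 0.694 with an estimated correlation. After median ratio scaling none of these 3 lists was called and their medians were -0.57, -0.67 and -0.52. Without any 1 of 1-B, 2-A, 2-B, L-A and L-C starch synthesis was not called (medians 0.56 to 0.69), nor flavonoids without any 1 of 1-C, 2-B, 2-C and L-B (0.33 to 0.42), nor senescence without any 1 of 2-A, 2-B and L-A (0.53 to 0.60). Starch breakdown (11 and 13 of 41, also when adjusted over the list alone; median -0.02) and defence proteins (8 and 7 of 22, also when adjusted over the list alone; median -0.14) were also called downward (camera adjusted p = 3.52e-04 and 0.0103, and adjusted p = 0.490 and 0.333 with an estimated correlation). With 1 contig per locus these 5 lists and the superoxide list were not called (medians 0.64, 0.99, 0.65, 0.07, -0.16 and 0.51), nor defence proteins after median ratio scaling (-1.19). With a filter of 50 the same 5 lists, starch synthesis, flavonoids, senescence, starch breakdown and defence proteins, were not called either (-0.26, 0.99, 1.67, -0.23 and -0.61). Flavonoids and senescence were not called with equal totals (-0.06 and 0.07), nor flavonoids with no filter (0.52). A contig like the ADP-glucose pyrophosphorylase subunit APL1 differed by -8.12 (Mm178893), one like the flavonol synthase FLS1 by -6.07 (Mm67310) and one like the anthocyanin transporter GSTF12 by 5.58 (Mm3360).

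Without L-A the log2 differences were larger for CRC (Mm734, 8.04 against 7.19), SEP1 (Mm1125, 8.12 against 7.30) and MYB21 (Mm414, 7.89 against 6.65). They were also larger for CWINV2 (Mm3, 9.16 against 8.02), Mm406 (9.27 against 8.42) and Mm1 (8.94 against 7.28). Those of other named contigs grew, stayed alike or shrank. Of the 50 heat shock contigs, read as a sign of handling, 26 were higher and 4 lower in codes 0, 1 and 2 (24 and 4 adjusted over the list alone; camera adjusted p = 0.923; median 1.19 as deposited and -0.01 after median ratio scaling). Of the 23 pollen and tapetum contigs 16 were higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.780; median 1.80, and 1.03 after median ratio scaling).

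In all, limma called 18073 contigs, 14470 higher and 3603 lower in codes 0, 1 and 2, so 80.1% of calls were higher. This share was 69.4% of 14522 calls with equal totals and 47.4% of 11146 calls after median ratio scaling. The median difference of all kept contigs was 1.2 as deposited, 0.73 with equal totals and 0.12 after median ratio scaling. The list medians, -3.91 for photosynthesis and 3.18 for the regulators as deposited, were -4.99 and 2.76 after median ratio scaling. Singly against code L, code 0 gave 16353 calls (78.7% higher; 44.0% after median ratio scaling), code 1 gave 17912 (79.1% higher; 67.6% with equal totals and 46.9% after median ratio scaling) and code 2 gave 17578 (77.7% higher; 65.8% with equal totals and 46.6% after median ratio scaling).

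**Figure D3:**
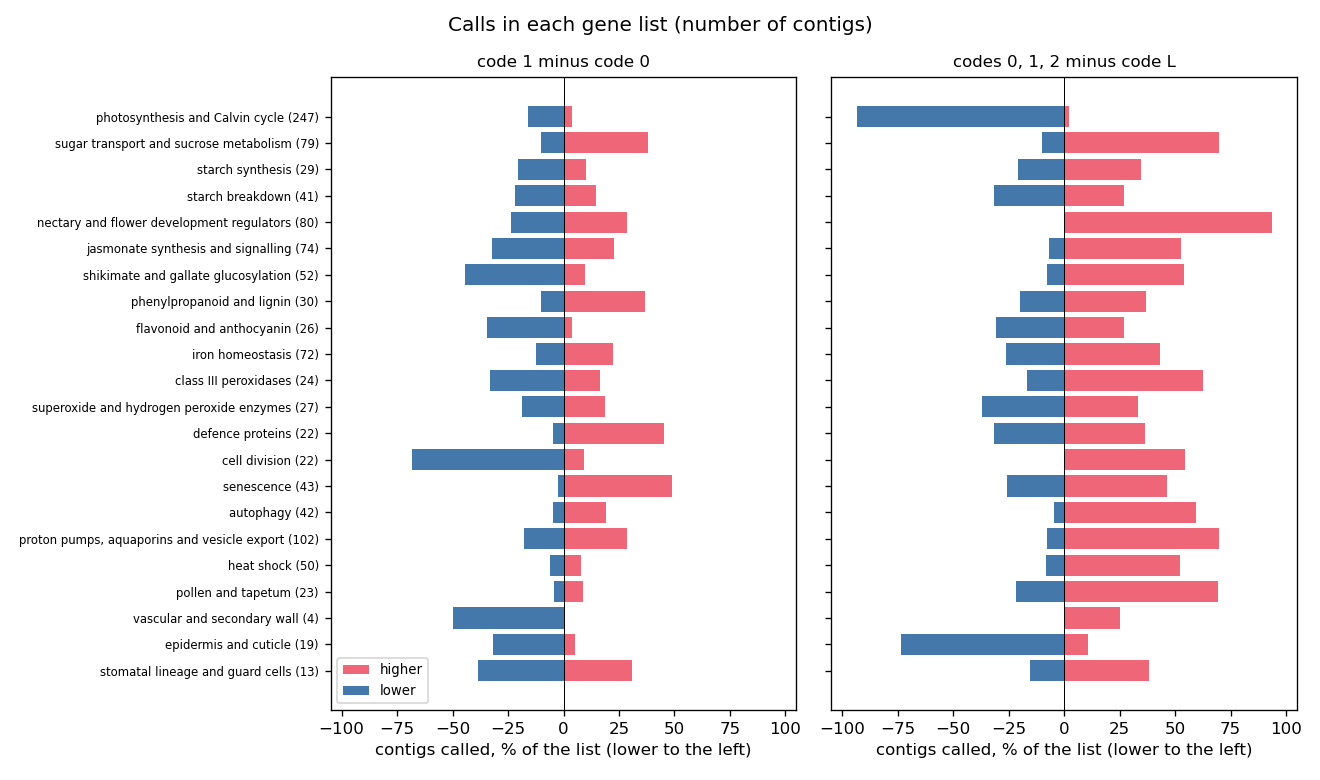
Share of each gene list's contigs called higher (red, right) or lower (blue, left), in percent of the list, for code 1 minus code 0 and for codes 0, 1 and 2 minus code L, with the number of contigs of each list in parentheses. Of 247 photosynthesis contigs 231 are lower in codes 0, 1 and 2 than in code L, and of 22 cell division contigs 15 are lower in code 1 than in code 0.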

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

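The removals of 2 libraries together were chosen after seeing the data; all other alternatives were planned. Setting aside grouping as filed, 5218 of 5663 checks of named contigs kept their direction and side of the threshold, 414 lost the call, 21 gained one and 10 moved. For gene lists 1696 of 1924 checks kept both, 108 lost the call, 42 gained one, 77 moved and 1 turned in camera's direction, which is relative to the other contigs. That 1 was starch breakdown, code 2 with 0, with a filter of 50 (not called, with a median of -0.28 against -0.81, both below 0). Checks in which a contig or list was called in neither fit count as kept. In the main fit only 8, 5, 12 and 9 of 21 lists passed in the comparisons tested, so many kept list checks were of uncalled lists. Of the 108 list calls lost, 32 were lost with an estimated correlation and 17 with 1 contig per locus. Counts are given in the order of codes 1 with 0, 2 with 1, 2 with 0, then codes 0, 1 and 2 with L, 0 with L, 1 with L and 2 with L, where 6734, 304, 6252, 18073, 16353, 17912 and 17578 contigs were called. With no filter they were 13187, 538, 11502, 32105, 29206, 32458 and 31116, and with a filter of 50 they were 2071, 93, 1954, 5369, 4903, 5365 and 5290, over more and fewer contigs. With a pseudocount of 10, 4290 (1 with 0), 3614 (2 with 0), 8872, 8757, 9992 and 10053 (against L: codes 0, 1 and 2, code 0, code 1 and code 2) were called, and with 0.1, 113 for code 2 with 1. Median ratio scaling gave 194 for code 2 with 1, 11146 for codes 0, 1 and 2 with L, 10112 for 0 with L and 11654 for 1 with L. With only the compared codes, code 2 with 1 gave 1 and 2 with 0 gave 4075, and library weights gave 1915 for code 2 with 1. Groups as filed gave 0, 0 and 0 by limma for codes 1 with 0, 2 with 1 and 2 with 0 (3557, 1263 and 5277 at an unadjusted p under 0.05). Leaving out 1 library gave 3955 to 7576, 0 to 1483, 3299 to 7208, 16701 to 18426, 13407 to 16844, 16722 to 18259 and 16440 to 17808; the 0 was without 1-A (limma; 2239 at an unadjusted p under 0.05), and a code left with 1 library is assumed to vary like the others. Without 2-A and 2-C code 2 with 1 gave 202, without L-A and 2-C 1444, and without 1-A and 1-B 6, with 2957 for code 1 with 0. Apart from the filters and the fits with fewer libraries, the cause was not tested. The letters were not treated as pairing libraries, since not every same-letter pair had deviations correlated above 0.1. Of 15 such pairs 8 did (-0.126 to 0.236), against 4 of 30 other pairs (-0.345 to 0.246), and 13 of the 15 were above 0. Of 11 libraries 7 had their highest r at their own letter. Deviations within a code sum to 0, so the pairs are not independent and the bar is hard to meet. A letter effect is a hint from the data and not the design, and the bar does not exclude it. With the letter as a replicate block the counts were 6742, 249, 6383, 18270, 16707, 18065 and 17768. The pollen list (code 2 with 0, median -0.76), starch synthesis (codes 0, 1 and 2 with L, 0.67) and Mm114371 (code 2 with 1, -4.80) were then not called, and Mm2212 (code 2 with 0, -2.75) was. Since the depth is unknown, what it limits cannot be stated; the spread between libraries limits calls of small differences.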

Other observations

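The tests of the filed labels, of L-A and of 2-A were chosen after seeing the results; the counts of other splits of the libraries were planned. Of 102 contigs of proton pumps, aquaporins and vesicle export, 29 rose and 18 fell from code 0 to code 1 (31 and 19 adjusted over the list alone; camera adjusted p = 0.211), with an aquaporin contig like PIP2.7 falling from 338 to 6.96 (Mm108923). Against code L, 71 were higher and 8 lower in codes 0, 1 and 2, also when adjusted over the list alone (camera adjusted p = 0.206). Of all 26053 kept contigs, 14470 were called higher in that comparison. The list's median was 1.47 as deposited and 0.42 after median ratio scaling, and an AHA2-like proton pump differed by 6.15 (Mm160). Of 42 autophagy contigs 8 rose and 2 fell in code 1 against 0, also when adjusted over the list alone (camera adjusted p = 0.0857). Against code L, 25 were higher and 2 lower (24 and 2 adjusted over the list alone, camera adjusted p = 0.520). The autophagy median was 1.35 as deposited and 0.28 after median ratio scaling. Of 13 stomatal contigs 4 rose and 5 fell in code 1 against 0 (5 and 7 adjusted over the list alone; camera adjusted p = 0.490): a contig like TMM, a receptor of the stomatal lineage, rose by 5.43 (Mm22137) and one like FAMA, a factor of guard cell fate, fell by 5.54 (Mm248379). Of 74 jasmonate contigs 39 were higher and 5 lower against code L, also when adjusted over the list alone (camera adjusted p = 0.787). The jasmonate median was 1.50 as deposited and 0.43 after median ratio scaling, with the repressor JAZ1 at 5.69 (Mm25184).

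Of 50 heat shock contigs, read as a sign of handling, 4 rose and 3 fell in code 1 against 0 (3 and 2 adjusted over the list alone; camera adjusted p = 0.643). The pollen and tapetum list had 2 of 23 higher and 1 lower in code 1 against 0 (2 and 0 adjusted over the list alone; camera adjusted p = 0.10), and the epidermis and cuticle list 1 of 19 higher and 6 lower (2 and 6 adjusted over the list alone; camera adjusted p = 0.252). Of the 4 vascular contigs, too few for a test, 2 were called by limma, both lower (2 lower and 1 higher adjusted over the list alone). Against code L, 12 of 22 cell division contigs were called by limma, all higher in the mean of codes 0, 1 and 2, also when adjusted over the list alone (camera adjusted p = 0.787). The median log2 difference of that list was 1.06 as deposited and 0.23 after median ratio scaling. Code 0 carried most of this difference. The list's mean log2 values were 4.18 and 4.34 in code 0, 1.81 to 2.05 in code 1, 1.47 to 1.79 in code 2 and 1.43 to 1.58 in code L. Of 30 phenylpropanoid contigs 11 were higher and 6 lower, also when adjusted over the list alone (camera adjusted p = 0.148), with a contig like PAL1, the entry enzyme of phenylpropanoids, higher in code L at a difference of -3.95 (Mm22331). The median of the phenylpropanoid list was 0.51 as deposited and -0.59 after median ratio scaling.

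The filed tissues and stages did not run with the values. If they were right, 1-A should resemble the other libraries filed as leaf, but its highest r with them was 0.544, against at least 0.930 with 1-B and 1-C. A candidate explanation is that tissues and stages were filed in another order than the codes: the photosynthesis list was higher in every code L library, filed as postsecretory nectary, than in any filed as leaf, by at least 3.11 on the log2 scale. The nectary and flower regulator list went the other way, at mean log2 values of 0.70 to 1.18 in code L and of 4.33 to 4.92 elsewhere. These values argue against the filed tissues, leaf for 0-A, 0-B and 1-A and nectary for code L. Which stage each of codes 0, 1 and 2 stands for was not tested.

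L-A held low values of contigs abundant in codes 1 and 2. Of 41 contigs at 100 or more in every code 1 and 2 library and at most 1 in L-B and L-C, 39 were above 0 in L-A, at a median of 1.167% of their mean in codes 1 and 2 (quartiles 0.855% to 1.54%). The values argue against an equal carry-over in all 3 code L libraries. This was examined over all 882 contigs at 100 or more in every code 1 and 2 library, whatever their code L values. The 5th percentile of this share was 1.4% in L-A (bootstrap 95% interval 1.13% to 1.65%), 0.184% in L-B (0.0931% to 0.332%) and 0.215% in L-C (0.126% to 0.536%). The bootstrap resampled contigs, so its intervals do not measure the spread between libraries. RNA or reads of a code 1 or 2 library in L-A may account for the low values there. No test here separates RNA from reads, and no biological explanation was tested.

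Shikimate and gallate contigs that fell from code 0 to code 1 were high again in 2-A. Over 23 of them, 2-A held a median of 77.1% of the excess of code 0 over code 1 (quartiles 11.9% to 92.9%), 2-B 10.5% and 2-C 0%. Tissue or RNA of code 0 in 2-A would bring cell division contigs too, but the 15 called ones regained a median of 1.69%. The title of 2-A says presecretory where its stage, like that of 2-B and 2-C, says secretory. Filed labels did not run with the values elsewhere, so this title says little about the stage of 2-A. A difference in stage stays open and could not be tested, since only 1 library of code 2 carries that title.

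For codes 0, 1 and 2 with L, the real grouping gave 18073 calls and the highest of the others among 100 splits drawn of 165 gave 7423. Thus 1 of 100, the real split itself, reached the real count. Every other split also dealt codes 0, 1 and 2 out anew among the remaining libraries. That can widen the spread within groups and lower the calls, so these splits cannot exclude chance in the grouping. Libraries of 1 code resemble each other and nothing says that they came from separate plants, so the splits do not test differences between plants or batches. For code 2 with 1 (304 calls; highest other split 179), 1 with L (17912; highest other 0) and 2 with L (17578; highest other 1), 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. Contigs matched to chloroplast-encoded loci made up 0.0786% to 0.106% of the total in codes 0, 1 and 2 and 0.180% to 0.298% in code L.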
